A study of Homo sapiens with 36 samples.

How the data were processed

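RNA-seq was measured in 36 libraries of human induced pluripotent stem cells taken through directed cardiac differentiation. The parental line was WTC, an established line that here carries mEGFP fused to ACTN2, the Z-disc protein alpha-actinin; it is called WT below. The other line was made from it by CRISPR/Cas9 and is heterozygous for a knockout of HSPG2, the gene of perlecan, a large heparan sulfate proteoglycan of basement membranes; it is called HSPG2 +/- below. Per the labels, each line was sampled at days 0, 6, 10, 15, 20 and 30 of a protocol aimed at left ventricular cardiomyocytes, with 3 libraries per line and day, giving 12 groups. The labels number the 3 libraries of a group but do not say whether they came from separate differentiations, so p-values measure only the spread between these libraries, part of which can be technical.

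Per the labels' protocols, RNA was extracted with Qiazol, polyA libraries were made with the KAPA mRNA Hyper Prep kit and sequencing was on a NovaSeq. Reads were processed with STAR and RSEM on GRCh38, per the submitters' processing notes; tool versions, the annotation release and the strand setting were not given in the sources used here. Each library has its own deposited table of genes with expected counts, the RSEM estimate of reads per gene in which a read shared between genes is split, so the values need not be whole. Of the values above 0, 16.0% were not whole numbers. The same deposited tables give TPM, a relative transcript abundance corrected for effective length, computed by the authors with RSEM. They also give FPKM, per the file headers, which was not used here. Expected counts were used for every test, and TPM only to describe levels. All 58735 gene identifiers were present in GENCODE release 29, which was used for symbols and GRCh38 coordinates, and 58207 had a symbol in a separate table of gene names. Because RSEM divides reads between similar genes, levels of close paralogs such as MYH6 and MYH7 carry that uncertainty, and without a stated strand setting reads of overlapping genes on opposite strands cannot be separated.

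The total of expected counts ranged from 18691875 to 35122150 per library. A count of 0 in a library allows up to about 3 counts, and this floor was used for folds against groups with no reads; it covers counting error only.

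Expected counts were rounded to whole numbers and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM factors and the filterByExpr filter by group, which left 19504 genes. All 36 libraries entered 1 fit with a mean for each of the 12 groups and 24 residual degrees of freedom. The comparisons were HSPG2 +/- against WT at each of the 6 days, each step between neighbouring days within WT, and the difference between the lines in their change from day 15 to day 30. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. SE denotes the standard error of a log2 fold change, and SD that of TPM over 3 libraries.

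Gene lists were tested with camera from limma 3.58.1, with an inter-gene correlation of 0.01 and adjustment over the 26 lists of a comparison. They covered pluripotency; mesoderm and early cardiac progenitors; sarcomere; cardiomyocyte maturation; calcium handling; cardiac ion channels and gap junctions; atrial and natriuretic genes; fatty acid oxidation; nuclear-encoded oxidative phosphorylation; glycolysis; basement membrane without HSPG2; fibrillar and interstitial matrix; heparan sulfate synthesis and other heparan sulfate proteoglycans; matrix receptors and adhesion; cell cycle; p53 targets; hypoxia and stress response; immediate early genes; imprinted genes; and markers of fibroblast and stromal, smooth muscle, endothelial, epicardial, endoderm and liver, neural and skeletal muscle cells. Camera was repeated with the correlation estimated from the data. Of all calls on lists, those that also passed with an estimated correlation were pluripotency, mesoderm, atrial, basement membrane, fibrillar matrix, stromal and neural lists from day 0 to day 6, pluripotency, atrial and fatty acid oxidation lists from day 6 to day 10, and, between the lines at day 10, stromal and skeletal muscle markers. The skeletal muscle list held 2 measured genes, with a median log2 fold change of -0.91 at day 10. Its call there was lost without WT replicate 2 or HSPG2 +/- replicate 1 or 2. A list's median is given a second time, with genes lacking reads in a group set to the bound from the floor, where this moved it.

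The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names HSPG2, a panel of 20 cardiac and pluripotency genes, the called genes of largest fold change with a mean of at least 5 TPM in 1 group and groups that do not overlap (10 each way between the lines at day 30, 5 each way on other days and in the interaction without the demand on overlap, 4 each way in a WT step), and the 2 called members of each list with the smallest p. Genes of the Y chromosome and XIST were left out. The text prints some of the genes that the rule names, and 1 called in the interaction is not reported here. Other genes are named only where it is said that they were chosen after their values were seen.

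The alternatives were relative log expression factors, no low-count filter, limma voom with a quality weight per group, DESeq2 1.42.0, a fit of the compared groups only, leaving out each library in turn, a threshold of 1 on the absolute log2 fold change, and a block for the replicate number within each day. Replicate numbers were checked for pairing by correlating, over genes, the deviations of same-numbered libraries of the lines from their group means. At day 20 these correlations were 0.20 to 0.57 and at day 30 they were 0.16 to 0.34. At these days the numbers were taken to pair the libraries, as an assumption that the values do not settle. The correlations of day 10 (0.06 to 0.23) and day 15 (-0.13 to 0.35) overlap with these, and libraries of unlike number were not compared. At day 30 replicate 1 stood apart from the others in both lines, which can give such values without pairing. The assumption comes from the data, since the labels state no pairing. Each of the 36 pairs of libraries within a group differed beyond sampling noise, with a chi-square per degree of freedom of 3.94 to 458.

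After the data were seen, 2 alternatives were added, because HSPG2 and other genes that separate the lines went against the labels of some libraries of days 20 and 30: a fit of the 24 libraries of days 0 to 15 (18719 genes, 16 residual degrees of freedom), and a fit without 6 doubted libraries (20439 genes). A score was computed for each library on 24 genes that separated the lines in the same direction at each of days 0, 6, 10 and 15 in the fit of those days, excluding HSPG2 and the genes left out by the rule for names. For each gene, log2 CPM values were scaled so that the mean of the WT libraries of days 0 to 15 was 0 and that of the HSPG2 +/- libraries was 1, and the median over the 24 genes was taken, with a 95% interval from 10000 resamplings of the genes. No library was moved between groups.

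The test was checked on simulated data with 50 changed genes at each of 4 fold changes, drawn from the real means, dispersions and library sizes with no other difference between the lines, for the line comparison at day 15. On 19258 genes edgeR recovered 24% of 1.5-fold, 74% of 2-fold, 94% of 4-fold and 96% of 8-fold changes, with 5 false calls among 149. The changed genes were picked only from genes with a simulated mean above 50 counts at day 15. The recovery of genes of lower count was not measured. Each simulated gene had the same dispersion in every group, whereas the real spread differed between groups. These rates therefore need not hold for the real fit. Plots were drawn with matplotlib, and tables were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.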

Results

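Gene expression was measured in 36 libraries from WT and HSPG2 +/- cells at days 0, 6, 10, 15, 20 and 30 of cardiac differentiation, with 3 libraries in each of the 12 groups. The total of expected counts ran from 18691875 in the WT library of day 30, replicate 2, to 35122150. The steps between days in WT describe the differentiation, the comparisons at each day ask where the lines differed, and the last comparison asks whether the lines differed in their late change, the stage of maturation that the study addresses. Folds and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another tool is named.

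HSPG2 (ENSG00000142798) lies on chromosome 1 at 21822245 to 21937297 of GRCh38, on the minus strand, and is annotated as protein coding. The labels do not give the edited position within it. In WT it stood at 16.6 ± 2.36 TPM at day 0 (SD, n = 3), 94.3 ± 9.01 at day 6, 94.9 ± 5.43 at day 10 and 80.4 ± 21.0 at day 15. In the libraries labelled HSPG2 +/- it stood at 2.96 ± 0.33, 19.2 ± 1.81, 16.2 ± 1.72 and 22.1 ± 2.14 TPM at these days, below every WT library of the same day. The log2 fold change was -2.46 at day 0 (SE 0.34, adjusted p = 0.000543), -2.26 at day 6 (SE 0.34, adjusted p = 0.0028), -2.33 at day 10 (SE 0.34, adjusted p = 0.0035) and -1.92 at day 15 (SE 0.33, adjusted p = 0.023). The call at day 6 was lost without HSPG2 +/- replicate 1, and that at day 10 without HSPG2 +/- replicate 1 or replicate 3. That at day 15 was lost in 5 of the 6 fits that left out 1 library of that day. These fits share their estimate of spread with the later days, when HSPG2 was uneven among libraries of some groups. At day 15 the HSPG2 +/- libraries held 19.73 to 23.95 TPM and the WT libraries 57.26 to 98.19 TPM. The lost calls therefore do not reflect the spread at these days alone.

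At day 30 HSPG2 went against the labels. The 3 libraries labelled WT at day 30 held 145.9, 48.4 and 47.4 TPM, and the 3 labelled HSPG2 +/- held 222.9, 163.3 and 162.9 TPM, so that HSPG2 was higher in the libraries labelled HSPG2 +/- (log2 fold change 1.31, SE 0.33, adjusted p = 0.0326), a call kept in 1 of 6 fits that left out 1 library. At day 20 the libraries labelled WT held 152.0, 175.5 and 142.4 TPM and those labelled HSPG2 +/- held 72.6, 38.2 and 96.2 TPM, with a log2 fold change of -1.35 (SE 0.33, adjusted p = 0.0856). With the replicate block, in which libraries of the same number are paired, the log2 fold change at day 20 was -1.39 and passed the test. The groups of days 20 and 30 are therefore called by their labels below, and every direction drawn from them carries this reservation.

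**Figure D1:**
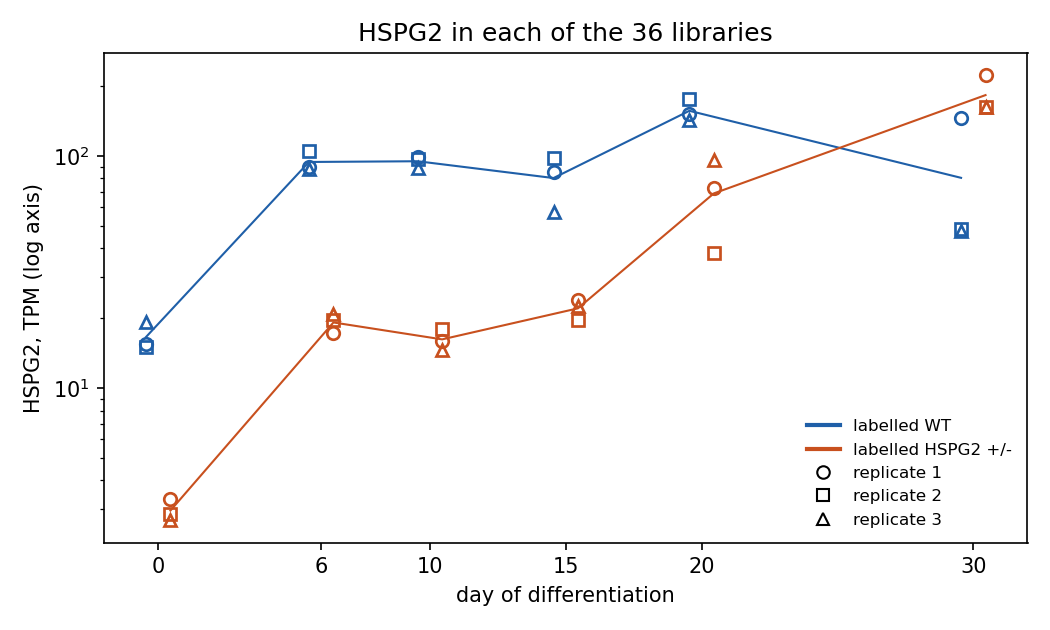
HSPG2 in TPM (vertical axis) in each of the 36 libraries by day of differentiation (horizontal axis), in blue for libraries labelled WT and orange for those labelled HSPG2 +/-, with circles, squares and triangles for replicates 1, 2 and 3. Up to day 15 all orange points lie below the blue ones, while at day 30 the orange points (162.9 to 222.9 TPM) lie above all blue ones (47.4 to 145.9 TPM).

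Other genes that separated the lines up to day 15 placed 6 of the 12 libraries of days 20 and 30 on the side of the other label. The line score over 24 genes other than HSPG2 ran from -0.25 to 0.14 in the 12 WT libraries of days 0 to 15 and from 0.82 to 1.07 in the 12 HSPG2 +/- libraries of those days, from which its genes were chosen. In the libraries labelled WT it was 0.23, 0.13 and 0.16 at day 20 and 0.04, 1.04 and 0.98 at day 30. In those labelled HSPG2 +/- it was 1.33, 1.36 and 0.22 at day 20 and 0.36, 0.12 and 0.22 at day 30. The genes scattered, and the 95% interval of the score lay wholly on the side of the other label in 3 of the 6 libraries: WT day 30 replicates 2 (0.81 to 1.54) and 3 (0.81 to 1.47), and HSPG2 +/- day 20 replicate 3 (-0.01 to 0.49). It reached past 0.5 in the 3 labelled HSPG2 +/- at day 30, up to 0.9, 0.55 and 0.63. The interval also crossed 0.5 in libraries on the side of their own label, WT day 30 replicate 1 (-0.13 to 0.9) and WT day 20 replicate 2 (-0.22 to 0.6). MGMT, a DNA repair gene chosen for mention after its values were seen, stood at 0.29, 4.08 and 5.55 TPM in the 3 libraries labelled WT at day 30 and at 0.64, 0.83 and 1.08 TPM in those labelled HSPG2 +/-. Single genes did not all follow the score: NNAT, an imprinted gene lower in HSPG2 +/- up to day 15, stood at 32.8 TPM in the library labelled HSPG2 +/- replicate 3 at day 20, below the 88.3 to 119 TPM of the libraries labelled WT. In that library 7 of the 24 genes lay nearer the HSPG2 +/- mean. At day 30 NNAT did part the libraries as the score did. WT replicates 2 and 3 held 10.6 and 19.7 TPM. WT replicate 1 held 42.6 TPM, and the libraries labelled HSPG2 +/- held 41.4, 40.9 and 39.1 TPM. All of these day 30 values lay below the 88.3 to 119 TPM of the libraries labelled WT at day 20.

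**Figure D2:**
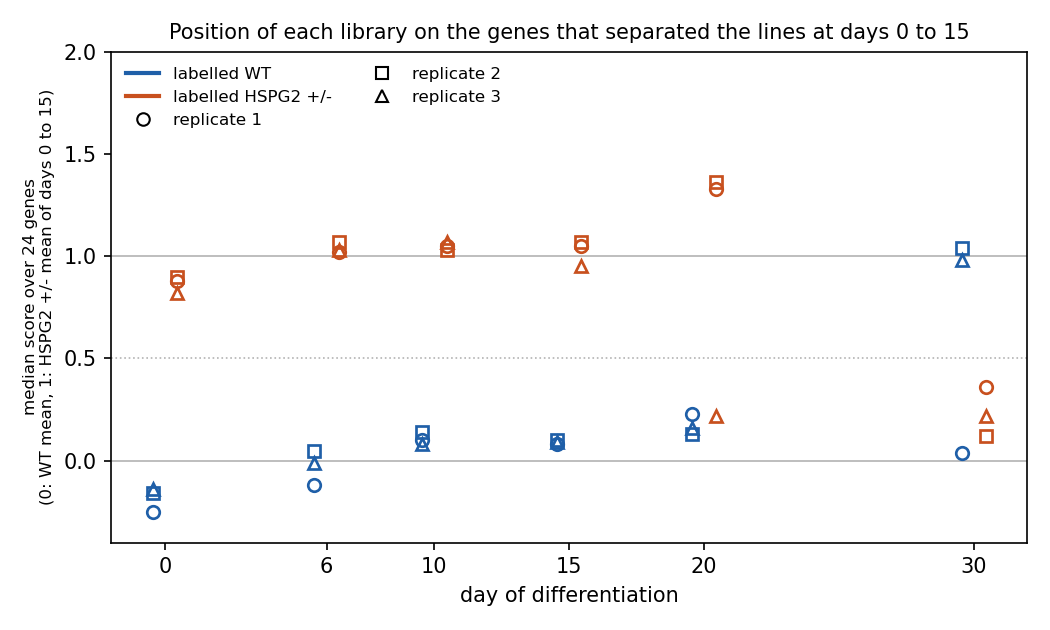
Line score of each library (vertical axis, no unit) by day of differentiation (horizontal axis), with 0 at the WT mean and 1 at the HSPG2 +/- mean of days 0 to 15, in blue for libraries labelled WT and orange for those labelled HSPG2 +/-. At day 30 the libraries labelled WT replicates 2 and 3 lie at 1.04 and 0.98 and the 3 labelled HSPG2 +/- lie at 0.12 to 0.36.

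From day 0 to day 6 WT cells lost pluripotency transcripts and gained those of cardiac mesoderm. POU5F1, a core pluripotency factor, fell from 1828 ± 338 to 38.1 ± 9.02 TPM (SD, n = 3; log2 fold change -5.79, SE 0.28, adjusted p = 6.18e-13), and the DNA methyltransferase DNMT3B fell by 4.79 on the log2 scale. GATA4, a cardiac transcription factor, rose from 0.387 ± 0.064 to 212 ± 12.1 TPM (log2 fold change 9.06, SE 0.35, adjusted p = 4.65e-18), and TNNT2, cardiac troponin T, rose from 3.73 ± 0.97 to 110.4 ± 30.8 TPM (log2 fold change 4.52, SE 0.65, adjusted p = 1.16e-06). HSPG2 rose by 2.39 on the log2 scale (SE 0.34, adjusted p = 7.9e-07). In all, 6082 genes rose and 5347 fell.

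Of the pluripotency list, 0 members rose and 13 of 15 fell between days 0 and 6, and of the mesoderm list 13 of 15 rose and 1 fell, with adjusted p = 5.95e-09 and 1.91e-08 for the lists. Of 25 sarcomere genes 19 rose, with a median log2 fold change of 4.55 (4.52 with genes at 0 held at their bound; adjusted p = 1.21e-05, and adjusted p = 0.453 with an estimated correlation). Of 11 atrial and natriuretic genes 8 rose (median 7.41, bounded 7.32, adjusted p = 7.39e-05), among them MYL4, an atrial myosin light chain, at least 1280-fold. Of 17 basement membrane genes other than HSPG2, 14 rose and 2 fell (median 1.76, adjusted p = 1.13e-05), with NID2, which encodes nidogen 2, up by 6.75. Of 22 fibrillar matrix genes 17 rose and 1 fell (median 3.51, bounded 2.96, adjusted p = 3.39e-08), with collagen COL1A1 at 798 ± 47.0 TPM after 14.7 ± 0.596. Each of these counts was the same when adjusted over the list alone.

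Markers of other cells moved in the same step. Of 11 endoderm and liver markers 9 rose, and 10 did when adjusted over the list alone. Their median was 11.01 (bounded 9.65, adjusted p = 0.000308, and adjusted p = 0.37 with an estimated correlation). TTR, which encodes the transport protein transthyretin, rose at least 2600-fold to 668 ± 56.1 TPM. Of 11 stromal markers 8 rose and 1 fell, and 9 rose and 1 fell when adjusted over the list alone. Their median was 6.40 (bounded 5.52, adjusted p = 1.13e-05). Of 9 epicardial markers 7 rose and 1 fell by both adjustments. Their median was 4.75 (bounded 4.55, adjusted p = 0.0115, and adjusted p = 0.164 with an estimated correlation). Of 7 neural markers 5 fell by both, among them PAX6. Their median was -4.08 (adjusted p = 0.0065). Of 32 oxidative phosphorylation genes 23 fell (median -0.77, adjusted p = 2.1e-06, and adjusted p = 0.334 with an estimated correlation). Of 21 cell cycle genes 14 fell (median -1.04, adjusted p = 0.00279, and adjusted p = 0.566 with an estimated correlation). Of 12 p53 targets 8 fell and 1 rose (median -1.20, adjusted p = 0.0166, and adjusted p = 0.495 with an estimated correlation). These 3 lists gave the same counts adjusted over the list alone. The heparan sulfate list (11 members up and 2 down by both adjustments) had adjusted p = 0.0538, and matrix receptors (7 up and 7 down by both) had adjusted p = 0.804.

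From day 6 to day 10 contractile and metabolic genes rose while proliferation genes fell. TNNT2 reached 786 ± 257 TPM (log2 fold change 2.76, SE 0.58, adjusted p = 0.000459), and the myosin heavy chains MYH6 and MYH7, close paralogs whose reads are hard to divide, reached 568 ± 202 and 50.1 ± 22.7 TPM (log2 fold changes 3.12 and 6.79, adjusted p = 0.00751 and 0.000128). COX6A2, a heart and muscle subunit of cytochrome oxidase, was without reads at day 6 and rose at least 15.3-fold to 11.5 ± 3.29 TPM. The proliferation marker MKI67 fell from 68.7 ± 6.21 to 19.4 ± 2.06 TPM (log2 fold change -1.91, SE 0.40, adjusted p = 0.000424), and POU5F1 fell to 0.437 ± 0.1 TPM. In all, 3285 genes rose and 3272 fell.

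Of 25 sarcomere genes 18 rose between days 6 and 10 by both adjustments. Their median was 2.76 (bounded 2.30, adjusted p = 6.65e-07, and adjusted p = 0.279 with an estimated correlation). Of 22 maturation genes 16 rose and 1 fell, and 18 rose and 1 fell when adjusted over the list alone. Their median was 2.82 (bounded 2.47, adjusted p = 6.1e-08, and adjusted p = 0.101 with an estimated correlation). Of 17 calcium handling genes 11 rose and 1 fell, and 13 rose and 1 fell when adjusted over the list alone. Their median was 1.55 (adjusted p = 7.53e-06, and adjusted p = 0.101 with an estimated correlation), with the sarcoplasmic reticulum regulators PLN and SLN up by 3.68 and 9.75. Of 24 fatty acid oxidation genes 14 rose by both adjustments, including CPT1B. Their median was 0.70 (adjusted p = 3.65e-06). Of 23 glycolysis genes 18 rose and 1 fell, and 19 rose and 1 fell when adjusted over the list alone. Their median was 1.38 (adjusted p = 2.52e-10, and adjusted p = 0.101 with an estimated correlation), with LDHA at 2971 ± 204 TPM after 390.1 ± 71.4. The hypoxia and stress list moved beside it, with 7 of 12 genes up and 1 down by both adjustments. Their median was 1.33 (adjusted p = 0.000457, and adjusted p = 0.132 with an estimated correlation), led by NDRG1 (log2 fold change 4.28). All 21 cell cycle genes fell by both adjustments. Their median was -1.51 (adjusted p = 2.52e-10, and adjusted p = 0.179 with an estimated correlation).

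Other cell markers also rose in this step. AFP, the fetal liver protein alpha-fetoprotein, rose from 19.5 ± 11 to 5059 ± 922 TPM (log2 fold change 8.13, SE 1.75, adjusted p = 0.000632). It was the only one of 11 endoderm and liver markers to pass by either adjustment (adjusted p = 0.514 for the list). Mean TPM in WT also went from 668 to 2103 for TTR, 344 to 1792 for APOA1 and 1.2 to 22.1 for ALB. Libraries of the earlier and later day did not overlap in these liver genes. They were picked after their values were seen, and levels of the other list members are not given here. The fit shares its estimate of spread with later days, when such genes were uneven among libraries of a label. The lack of further calls therefore does not show that these genes stayed level. Of 10 endothelial markers 9 rose and 1 fell by both adjustments. Their median was 2.40 (adjusted p = 0.000457, and adjusted p = 0.101 with an estimated correlation). Of 9 epicardial markers 4 rose by both, among them WT1 and TBX18. Their median was 1.59 (adjusted p = 0.0113, and adjusted p = 0.132 with an estimated correlation). Of 13 imprinted genes 8 rose by both, including the growth factor IGF2 and H19. Their median was 1.38 (adjusted p = 0.00234, and adjusted p = 0.179 with an estimated correlation). The ion channel list rose with a median of 1.15 (9 members up and 3 down, 10 and 3 when adjusted over the list alone, adjusted p = 0.0373, and adjusted p = 0.179 with an estimated correlation), a call lost without WT day 10 replicate 1.

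From day 10 to day 15 MYL2 and smooth muscle markers rose and glycolysis genes fell. MYL2, the ventricular myosin light chain, rose from 0.137 to 30.4 ± 6.76 TPM (log2 fold change 8.17, SE 1.54, adjusted p = 0.000384), and PLN rose from 23.6 ± 5.75 to 134 ± 25.1 TPM (log2 fold change 2.77, SE 0.64, adjusted p = 0.00244). As a list, sarcomere genes did not pass, with a median of 0.83 and 1 member up and 1 down by both adjustments (adjusted p = 0.103). ACTG2, a smooth muscle actin, rose from 2.29 ± 0.977 to 283 ± 110.1 TPM, and 5 of 9 smooth muscle markers rose by both adjustments. Their median was 1.31 (adjusted p = 0.026, and adjusted p = 0.572 with an estimated correlation), a list call lost without WT day 15 replicate 2. In all, 2836 genes rose and 2626 fell.

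Of 23 glycolysis genes 16 fell between days 10 and 15 by both adjustments. Their median was -1 (adjusted p = 9.87e-08, and adjusted p = 0.192 with an estimated correlation), with hexokinase HK2 at 26.2 ± 2.83 TPM after 96.1 ± 6.11. Of 12 hypoxia and stress genes 8 fell by both. Their median was -1.83 (adjusted p = 1.83e-07, and adjusted p = 0.116 with an estimated correlation). Of 21 cell cycle genes 9 rose, and 10 rose when adjusted over the list alone, among them TYMS and PCNA, which serve DNA synthesis. Their median was 0.60 (adjusted p = 0.00204, and adjusted p = 0.594 with an estimated correlation). Of 20 matrix receptor genes 10 rose and 1 fell by both adjustments. Their median was 0.61 (adjusted p = 0.00204, and adjusted p = 0.234 with an estimated correlation), with integrin ITGA1 up by 3.23. Stromal markers rose, 7 up and 1 down, and 8 and 1 when adjusted over the list alone. Their median was 0.92 (adjusted p = 0.00962, and adjusted p = 0.187 with an estimated correlation), with the proteoglycan DCN at 443 ± 45.7 TPM after 75.1 ± 28.5. The endothelial list was also called, with a median of -1.25, but did not pass with an estimated correlation. Its call was lost without WT day 15 replicate 2. The skeletal muscle list, of which 2 genes were measured, fell with 1 member by both adjustments. Their median was -2.57 (adjusted p = 0.0422, and adjusted p = 0.187 with an estimated correlation), and this call was lost on leaving out any 1 of the 6 libraries.

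From day 15 to day 20 cardiomyocyte transcripts fell in the libraries labelled WT. TNNT2 fell from 1434 ± 142 to 116 ± 45.2 TPM (SD, n = 3; log2 fold change -3.55, SE 0.59, adjusted p = 6.08e-05), MYH6 fell from 676 ± 167 to 10.6 ± 7.41 TPM (log2 fold change -6.04, SE 1.02, adjusted p = 6.97e-05), and TNNI3, the adult cardiac troponin I, fell from 17.2 ± 3.54 to 1.12 ± 0.262 TPM (log2 fold change -4.63, SE 0.67, adjusted p = 9.93e-06). CDKN1A, a cell cycle inhibitor induced by p53, rose from 26.0 ± 10.8 to 234 ± 62.4 TPM (log2 fold change 3.14, SE 0.53, adjusted p = 6.74e-05). HSPG2 rose by 1.14 (SE 0.32, adjusted p = 0.00857), a call lost without WT day 15 replicate 3. In all, 2794 genes rose and 3348 fell.

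Of 25 sarcomere genes 22 fell between days 15 and 20, and 23 fell when adjusted over the list alone. Their median was -3.55 (adjusted p = 1.33e-10, and adjusted p = 0.238 with an estimated correlation). Of 22 maturation genes 16 fell, and 18 fell when adjusted over the list alone. Their median was -2.33 (adjusted p = 1.99e-07, and adjusted p = 0.163 with an estimated correlation). Calcium handling genes fell with 10 members down and 2 up, and 11 and 2 when adjusted over the list alone. Their median was -1.44 (adjusted p = 0.00168, and adjusted p = 0.238 with an estimated correlation). Of 32 oxidative phosphorylation genes 18 fell, and 23 fell when adjusted over the list alone. Their median was -0.47 (adjusted p = 2.03e-07, and adjusted p = 0.238 with an estimated correlation). Fatty acid oxidation genes fell with 11 members down and 1 up by both adjustments. Their median was -0.39 (adjusted p = 0.0111, and adjusted p = 0.235 with an estimated correlation), a call lost without WT day 15 replicate 1. Cell cycle genes fell with 9 members by both adjustments. Their median was -0.63 (adjusted p = 0.00155, and adjusted p = 0.514 with an estimated correlation). Of 12 p53 targets 7 rose, and 9 rose when adjusted over the list alone. Their median was 1.07 (adjusted p = 0.000129, and adjusted p = 0.238 with an estimated correlation).

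Markers of other cells moved both ways in that step. Of 10 endothelial markers 7 fell, and 8 fell when adjusted over the list alone. Their median was -3.28 (bounded -2.52, adjusted p = 0.000104, and adjusted p = 0.124 with an estimated correlation), with CDH5, the endothelial cadherin, at 0.023 ± 0.04 TPM after 5.09 ± 1.39. Of 11 stromal markers 7 rose and 2 fell by both adjustments. Their median was 1.29 (adjusted p = 0.0272, and adjusted p = 0.238 with an estimated correlation), a call lost without WT day 15 replicate 1. Fibrillar matrix genes rose with 10 members up and 1 down, and 11 and 1 when adjusted over the list alone. Their median was 0.61 (adjusted p = 6.97e-05, and adjusted p = 0.124 with an estimated correlation), with COL1A1 at 2998 ± 216 TPM. Endoderm and liver markers had adjusted p = 0.0818, with 0 members up and 0 down by edgeR, and the libraries labelled WT at day 20 were uneven in AFP, named here and for days 20 and 30 below after its values were seen, at 339, 470 and 12573 TPM.

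From day 20 to day 30 sarcomere genes rose in the libraries labelled WT, of which replicates 2 and 3 of day 30 went against their label in HSPG2 and in the line score. TNNI3 rose to 19 ± 14.8 TPM (log2 fold change 4.52, SE 0.67, adjusted p = 3.72e-05) and MYL2 from 6.76 ± 3.85 to 152 ± 130.1 TPM (log2 fold change 4.29, SE 1.05, adjusted p = 0.00643). The direction of MYL2 rested on the doubted libraries: it was at 2.87 TPM in replicate 1 of day 30, and without the doubted libraries its log2 fold change was -1.28. TNNT2 at day 30 was 55.0 TPM in replicate 1 and 427 and 351 TPM in replicates 2 and 3. TNNI3 at day 30 was likewise 2.43 TPM in replicate 1 and 31.1 and 23.4 TPM in replicates 2 and 3. In all, 1914 genes rose and 1545 fell, against 1834 calls without WT day 20 replicate 1, 1688 without WT day 30 replicate 2 and 2276 without the 6 doubted libraries. Of the 2276, 1141 were shared with the calls on all libraries, 8 of these with the opposite sign.

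Of 25 sarcomere genes 10 rose between days 20 and 30, and 15 rose when adjusted over the list alone. Their median was 1.86 (adjusted p = 0.00044, and adjusted p = 0.567 with an estimated correlation). Without the doubted libraries the list went the other way (adjusted p = 0.0027). Of 22 maturation genes 10 rose, and 15 rose when adjusted over the list alone. Their median was 1.74 (adjusted p = 0.00044, and adjusted p = 0.51 with an estimated correlation), and this list also went the other way without the doubted libraries (adjusted p = 0.413). Fibrillar matrix genes rose with 12 of 22 members, and 16 rose and 3 fell when adjusted over the list alone. Their median was 0.80 (adjusted p = 3.01e-06, and adjusted p = 0.0657 with an estimated correlation), with the proteoglycan BGN up by 3.89. Basement membrane genes rose with 7 members up and 1 down, and 7 and 2 when adjusted over the list alone. Their median was 0.39 (adjusted p = 0.00881, and adjusted p = 0.302 with an estimated correlation), with COL15A1 up by 4.85. Immediate early genes rose with 4 of 11 members by both adjustments, among them NR4A1 and EGR2. Their median was 0.76 (adjusted p = 0.00044, and adjusted p = 0.437 with an estimated correlation). Cell cycle genes fell with 7 members, and 10 when adjusted over the list alone. Their median was -0.67 (adjusted p = 0.00044, and adjusted p = 0.567 with an estimated correlation). The endothelial and stromal lists were also called in this step, with medians of 1.58 (bounded 0.88) and 0.67. Neither passed with an estimated correlation, and the stromal call was lost without WT day 20 replicate 3 or WT day 30 replicate 1.

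**Figure D3:**
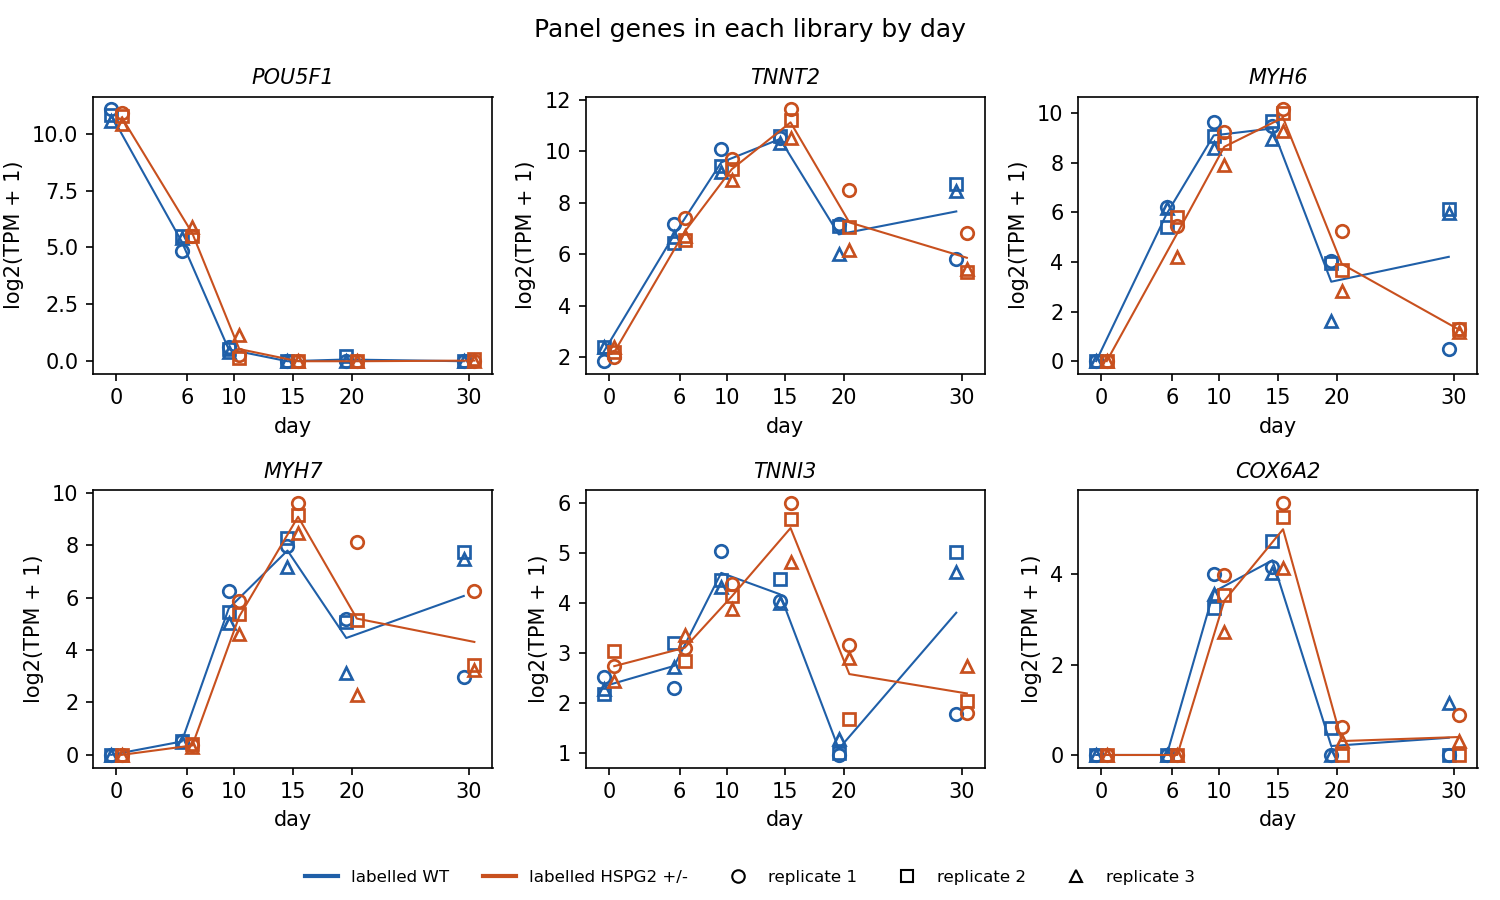
Expression of POU5F1, TNNT2, MYH6, MYH7, TNNI3 and COX6A2 as log2(TPM + 1) on the vertical axis by day of differentiation, with points for libraries and lines for group means, in blue for libraries labelled WT and orange for those labelled HSPG2 +/-. TNNT2 in WT runs from 3.73 TPM at day 0 to 1434 TPM at day 15 and 116 TPM at day 20, and its libraries part at day 30.

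Between the lines, edgeR on all libraries called few genes at days 0 to 15, fewer than the fit of those days alone, given below. NNAT, which encodes neuronatin, was called at each of these days. At day 0 NNAT stood at 46.3 ± 4.92 TPM in HSPG2 +/- and 302 ± 8.99 TPM in WT (SD, n = 3 each; log2 fold change -2.71, SE 0.27, adjusted p = 2.9e-06). The fit of all libraries shares its estimate of spread with days 20 and 30. In the fit of days 0 to 15 the SE of this fold was 0.099. SLC15A4, a lysosomal transporter, stood at 2.34 ± 0.48 and 10.1 ± 0.195 TPM (log2 fold change -2.15, SE 0.31, adjusted p = 0.000593), and the zinc finger gene ZNF676 at 15.7 ± 1.45 and 1.86 ± 0.411 TPM (log2 fold change 3.03, SE 0.54, adjusted p = 0.0123). Including HSPG2, 8 genes were higher and 7 lower at day 0, and 432 genes passed an unadjusted p of 0.05. NNAT differed again by -2.15 at day 6 (adjusted p = 0.000226), -1.72 at day 10 (adjusted p = 0.0058) and -2.19 at day 15 (adjusted p = 0.000172). The call for NNAT was lost at day 10 without HSPG2 +/- replicate 1 or replicate 3 and was kept on leaving out any other library of these days. ZNF676 at day 0 was kept in 2 of the 6 fits that left out 1 library.

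At day 6, 3 genes were higher and 3 lower in HSPG2 +/-, at day 10 there were 1 and 4, and at day 15 there were 1 and 4. With relative log expression factors day 6 had 1 and 2. Of the genes lower at day 0, 3 were also lower at day 6, where 0.00108 would be shared by independent lists, and 4 were also lower at day 15, where 0.00144 would be. These counts fell when 1 library was left out, except for day 15 without WT replicate 3, where there were 5. At day 0 they were 6, 8 and 9 without WT replicates 1, 2 and 3, and 10, 8 and 9 without HSPG2 +/- replicates 1, 2 and 3. At day 6 they were 3, 2 and 2 without WT replicates 1, 2 and 3, and 3, 2 and 3 without HSPG2 +/- replicates 1, 2 and 3. At day 10 they were 2 without any 1 WT library and without HSPG2 +/- replicate 2, and 0 by edgeR without HSPG2 +/- replicate 1 (467 genes at an unadjusted p under 0.05) or replicate 3 (349 genes). At day 15 they were 2 and 1 without WT replicates 1 and 2, and 1, 2 and 1 without HSPG2 +/- replicates 1, 2 and 3. A fit of the 24 libraries of days 0 to 15, chosen after seeing the data, gave 66, 76, 94 and 186 genes at days 0, 6, 10 and 15, and DESeq2 on all libraries gave 38, 26, 29 and 30. Limma voom with quality weights per group gave 276, 76, 262 and 11, and edgeR on the compared groups only gave 257, 43, 119 and 12.

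Among the gene lists none passed between the lines at day 0. At day 6 endothelial markers were lower in HSPG2 +/- (median -1.45, bounded -0.73, adjusted p = 1.02e-05, and adjusted p = 0.128 with an estimated correlation), with 0 of 10 members past the test over all genes by edgeR and 1 lower when adjusted over the list alone. In the fit of days 0 to 15 alone 5 members fell and the list held with an estimated correlation (adjusted p = 0.0103). Stromal markers were higher at day 6 (median 0.26, adjusted p = 0.0457, and adjusted p = 0.578 with an estimated correlation), a call lost without WT replicate 2 or 3 or HSPG2 +/- replicate 1 or 3, and at day 10 (median 0.33, adjusted p = 8.46e-05), with 0 members past the test over all genes or adjusted over the list alone.

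At day 10 glycolysis genes were lower in HSPG2 +/- (median -0.31, adjusted p = 1.66e-09, and adjusted p = 0.171 with an estimated correlation). Hypoxia and stress genes were lower too (median -0.33, adjusted p = 0.00425, and adjusted p = 0.367 with an estimated correlation). Fibrillar matrix genes were higher (median 0.27, adjusted p = 3.23e-05, and adjusted p = 0.0543 with an estimated correlation), as were cell cycle genes (median 0.20, adjusted p = 0.00173, and adjusted p = 0.795 with an estimated correlation). No member of these 4 lists passed over all genes or adjusted over the list alone, and the hypoxia call was lost without HSPG2 +/- replicate 2. At day 15 sarcomere genes were higher in HSPG2 +/- (median 0.76, adjusted p = 0.000105), as were maturation genes (median 0.72, adjusted p = 0.00028) and glycolysis genes (median 0.28, adjusted p = 0.000112), each with adjusted p = 0.652 with an estimated correlation and no member past the test by either adjustment. Imprinted genes were lower (median -0.16, adjusted p = 0.0367, and adjusted p = 0.652 with an estimated correlation), a call lost without WT replicate 1 or 2 or HSPG2 +/- replicate 1. Endoderm and liver markers did not pass (median -0.66, adjusted p = 0.316). The maturation call was lost without HSPG2 +/- replicate 1, and the glycolysis call without that library or WT replicate 3. Of the HSPG2 +/- libraries of day 15, replicate 3 held the least TNNT2 (1470 TPM, against 3197 and 2384) and the most AFP (12106 TPM, against 5660 and 5592), named here after its values were seen. WT replicate 3 of day 15 stood apart in the share of counts from mitochondrially encoded genes, 8.53%, where the other 5 libraries of the day held 3.66 to 4.43%.

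**Figure D4:**
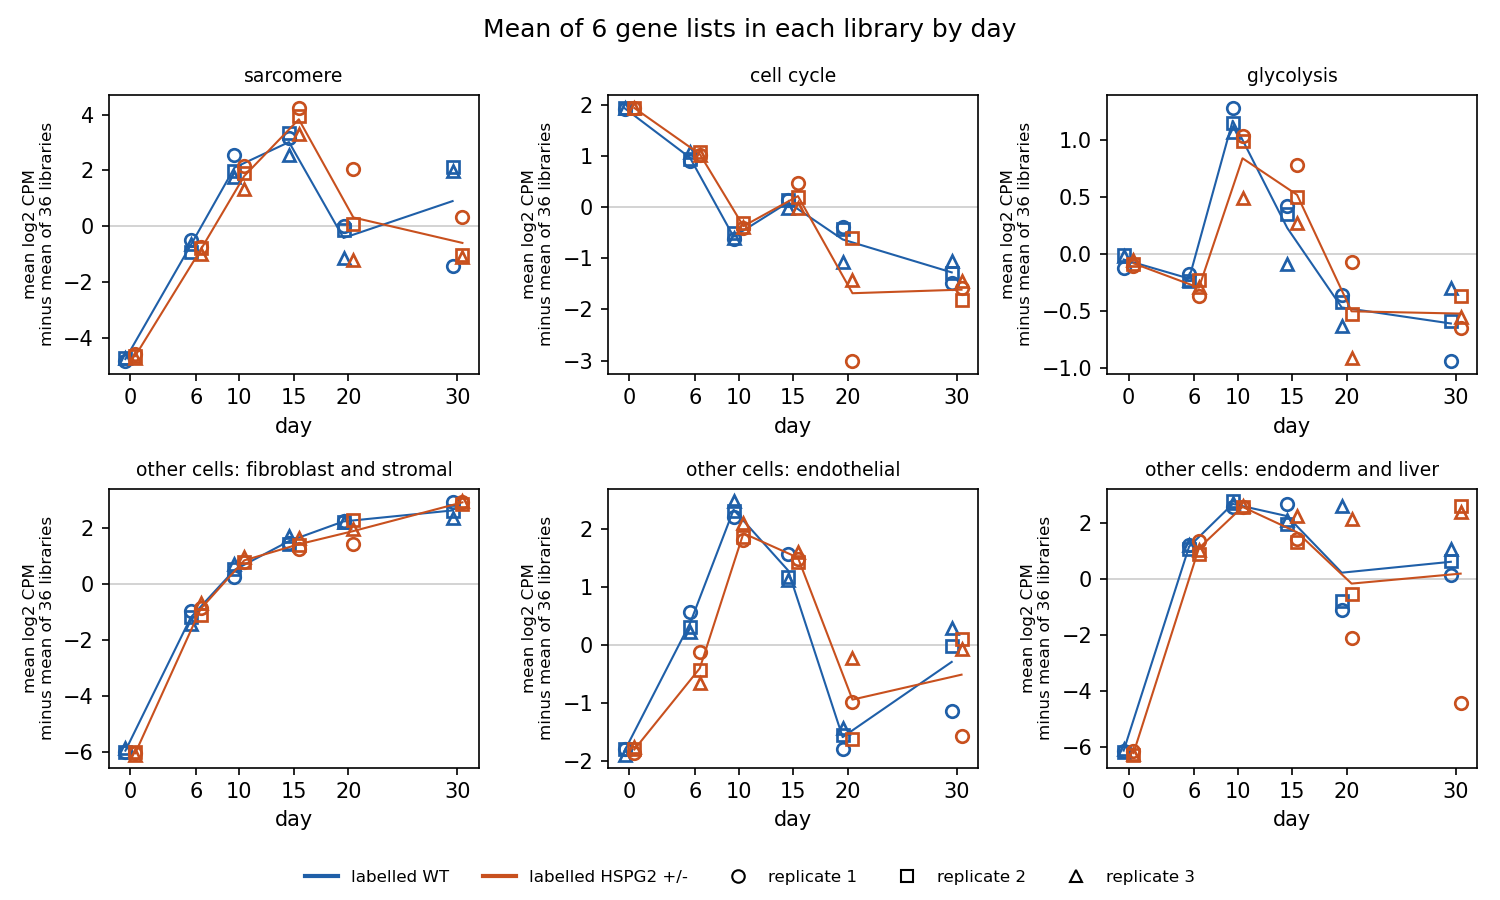
Mean log2 CPM of 6 gene lists (sarcomere, cell cycle, glycolysis, stromal, endothelial, and endoderm and liver), less the mean of the 36 libraries, on the vertical axis by day of differentiation, with points for libraries and lines for group means, in blue for libraries labelled WT and orange for those labelled HSPG2 +/-. At day 30 the sarcomere values of the libraries labelled WT are -1.41, 2.12 and 1.99, against 0.33, -1.04 and -1.09 in those labelled HSPG2 +/-.

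At day 20, NNAT was lower in the libraries labelled HSPG2 +/- at 25.9 ± 6.26 TPM against 107 ± 16.1 TPM (SD, n = 3 each; log2 fold change -2.20, SE 0.27, adjusted p = 0.000175), a call kept on leaving out any 1 library of that day. PTTG1, which encodes securin, a regulator of chromosome separation, was also lower (log2 fold change -0.97, SE 0.18, adjusted p = 0.0276), and LENG8 was higher (log2 fold change 1.07, SE 0.19, adjusted p = 0.0248). The call for PTTG1 was lost without WT replicate 1 or 2 or HSPG2 +/- replicate 3, and that for LENG8 without WT replicate 1. In all, 4 genes were higher and 4 lower, and 2672 passed an unadjusted p of 0.05. The count moved to 2 and 4 without WT replicates 1 and 2, and to 204, 934 and 51 without HSPG2 +/- replicates 1, 2 and 3. With the replicate block, which pairs the libraries at this day, 65 genes were higher and 26 lower, and without the doubted libraries 521 were higher and 290 lower.

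Cell cycle genes were lower in the libraries labelled HSPG2 +/- at day 20, with 0 of 21 members past the test over all genes by edgeR and 14 lower when adjusted over the list alone. Their median was -0.78 (adjusted p = 4.97e-19, and adjusted p = 0.54 with an estimated correlation). HSPG2 +/- replicate 1 stood apart, with MKI67 at 2.14 TPM where replicates 2 and 3 held 25 and 12.7 TPM and the libraries labelled WT 23.6, 30.4 and 14.2 TPM, but the list call was kept on leaving out any 1 library. Imprinted genes were lower (median -0.21, adjusted p = 0.00187, and adjusted p = 0.641 with an estimated correlation), a call lost without HSPG2 +/- replicate 1. Sarcomere genes were higher, with 1 of 25 members past the test when adjusted over the list alone. Their median was 1.49 (adjusted p = 0.00177, and adjusted p = 0.727 with an estimated correlation), a call lost without WT replicate 3 (adjusted p = 0.129). Without HSPG2 +/- replicate 1 the list went the other way (adjusted p = 0.899), so that its direction rested on that library. The libraries labelled HSPG2 +/- were uneven in these genes, with TNNT2 at 361, 134 and 70.3 TPM, and in liver markers, with AFP at 61.5, 935 and 18357 TPM. The call for calcium handling genes (median 0.45, adjusted p = 0.0381, and adjusted p = 0.641 with an estimated correlation) had adjusted p = 0.0738 with the replicate block. It was also lost without WT replicate 3 or HSPG2 +/- replicate 1.

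At day 30, 109 genes were higher and 270 lower in the libraries labelled HSPG2 +/-, in which HSPG2 itself went against the label. MOXD1, a copper monooxygenase, was lower at 0.813 ± 0.085 against 16.0 ± 12.9 TPM (SD, n = 3 each; log2 fold change -4.09, SE 0.56, adjusted p = 0.000263), and LIN28A, an RNA-binding protein of early development, by -3.64 (SE 0.47, adjusted p = 0.000236). Of the genes named by size, 3 that interferon induces were higher, although no list of such genes was tested. IFI6 stood at 93.4 ± 59.4 against 19.3 ± 4.42 TPM (log2 fold change 2.34, SE 0.32, adjusted p = 0.000242). MX1 stood at 18.1 ± 14.7 against 2.95 ± 0.711 TPM (log2 fold change 2.85, SE 0.54, adjusted p = 0.00849) and ISG15 at 23.7 ± 8.81 against 6.50 ± 1.60 TPM (log2 fold change 1.95, SE 0.48, adjusted p = 0.0308). MOXD1, LIN28A and IFI6 were kept on leaving out any 1 library of the day, MX1 in 4 of these 6 fits and ISG15 in 2. The genes named here by size had all 3 libraries of 1 label above all 3 of the other, an order that chance gives to 10% of genes.

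The sarcomere and maturation lists were lower in the libraries labelled HSPG2 +/- at day 30, with few members passing over all genes. The calcium handling, ion channel and atrial lists were not called (medians -0.39, -0.58 and -0.62). By mean log2 CPM of the sarcomere list, WT replicate 1 lay below all 3 libraries labelled HSPG2 +/-. MYH6 stood at 1.40 ± 0.133 TPM against 0.42, 69.0 and 61.9 TPM in the 3 libraries labelled WT (log2 fold change -4.82, SE 0.98, adjusted p = 0.0122), so that 2 of these 3 were above it, and both were doubted. Of 25 sarcomere genes 3 fell, and 18 fell when adjusted over the list alone. Their median was -1.88 (adjusted p = 6.17e-08, and adjusted p = 0.885 with an estimated correlation). Of 22 maturation genes 3 fell, and 9 fell and 1 rose when adjusted over the list alone. Their median was -1.62 (adjusted p = 0.00933, and adjusted p = 0.885 with an estimated correlation), a call lost without WT replicate 2 or 3. Immediate early genes were lower, with 2 of 11 members, EGR2 and NR4A1, and 4 when adjusted over the list alone. Their median was -0.65 (adjusted p = 0.000818, and adjusted p = 0.885 with an estimated correlation). Imprinted genes were higher, with 0 of 13 members over all genes by edgeR and 5 when adjusted over the list alone. Their median was 0.42 (adjusted p = 0.000818, and adjusted p = 0.885 with an estimated correlation). The basement membrane list had adjusted p = 0.853, with NID2 higher by 0.75 over all genes and 1 member higher and 1 lower when adjusted over the list alone. The heparan sulfate list had adjusted p = 0.853, with SULF1, which removes sulfate groups from heparan sulfate, lower (log2 fold change -1.94), and 1 member higher and 3 lower when adjusted over the list alone. Of 9 epicardial markers 3 were lower by both adjustments, among them TBX18 and ALDH1A2 (log2 fold changes -3.46 and -3.08), but the list did not pass (median 0.21, adjusted p = 0.48). Liver markers were uneven, with AFP at 19.4, 15467 and 14046 TPM in the libraries labelled HSPG2 +/-. With the replicate block, which pairs the libraries at this day, the calls for MYH6, EGR2, SULF1 and TBX18 were lost, at log2 fold changes of -3.90, -1.44, -1.89 and -2.79. Each call on a gene in this paragraph, for MYH6, EGR2, NR4A1, NID2, SULF1, TBX18 and ALDH1A2, was lost without WT replicate 2 or 3 or HSPG2 +/- replicate 2 or 3, and so kept in 2 of 6 fits.

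The count of 379 genes at day 30 rested on single libraries: it was 2658, 21 and 38 without WT replicates 1, 2 and 3, and 1403, 27 and 40 without HSPG2 +/- replicates 1, 2 and 3. The excess of lower genes did not hold throughout, with 1366 higher and 1292 lower without WT replicate 1, and 694 and 709 without HSPG2 +/- replicate 1. There were 523 genes with the replicate block, of which 235 were shared with the 379. DESeq2 gave 1021 genes, and limma voom with quality weights per group gave 0, with 1197 genes at an unadjusted p under 0.05.

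The change from day 15 to day 30 differed between the labelled lines for 98 genes. The log2 change in HSPG2 +/- less that in WT was positive for 30 of them and negative for 68. This difference was 3.23 for HSPG2 (SE 0.46, adjusted p = 0.000454), 2.97 for NNAT (SE 0.38, adjusted p = 0.000118), 2.44 for SLC15A4 (SE 0.42, adjusted p = 0.00453) and -4.50 for MGMT (SE 0.79, adjusted p = 0.00453). NNAT went from 35.2 to 40.5 TPM in the libraries labelled HSPG2 +/- and from 145 to 24.3 TPM in those labelled WT, so its difference came mostly from the latter. These 4 calls were kept in all 12 fits that left out 1 library. For TNNI3 the difference was -3.95 (SE 0.78, adjusted p = 0.0156), a call kept in 7 of 12, with 46.6 and 3.73 TPM at days 15 and 30 in the libraries labelled HSPG2 +/- and 17.2 and 19 TPM in those labelled WT. Among sarcomere genes it was negative for 1 of 25 over all genes and for 20 when adjusted over the list alone. Their median difference was -2.64 (adjusted p = 1.92e-12, and adjusted p = 0.448 with an estimated correlation). Among the imprinted genes of the list, which does not hold NNAT, it was positive for 0 of 13 over all genes by edgeR and for 6 when adjusted over the list alone. Their median difference was 0.70 (adjusted p = 1.58e-05, and adjusted p = 0.411 with an estimated correlation). As these directions compare labels of which 5 at day 30 went against the line score, they are given for the labels only.

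The count of 98 genes was 42, 61 and 54 without WT day 15 replicates 1, 2 and 3, and 1647, 27 and 29 without WT day 30 replicates 1, 2 and 3. It was 28 and 40 without HSPG2 +/- day 15 replicates 1 and 2, and 568, 30 and 43 without HSPG2 +/- day 30 replicates 1, 2 and 3. The excess of negative differences did not hold throughout, with 861 positive and 786 negative without WT day 30 replicate 1. With the replicate block there were 276 genes, 129 positive and 147 negative, of which 76 were shared with the 98. DESeq2 gave 387, and 2412 genes passed an unadjusted p of 0.05.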

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

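The test of labels by genes other than HSPG2 was written before its result was seen; the other tests in this part, the splits of the libraries among them, were chosen only after. The results listed here were singled out because the change from day 15 to day 30 differed between the lines as labelled, by a test of that difference (an interaction), and all carry the conflict of labels described with HSPG2. The test called 98 genes. On the log2 scale, the change in HSPG2 +/- less that in WT was 3.23 for HSPG2, -3.95 for TNNI3, -8.49 for MYH11, a smooth muscle myosin, -5.14 for NMRK2, -4.50 for MGMT, -4.48 for SPOCK2, 5.97 for LEAP2, 2.97 for NNAT, 2.44 for SLC15A4 and 2.28 for IFI6. It was -1.98 for COL18A1, -2.72 for FABP3, 1.71 for NDRG1, -3.87 for TBX5, -1.32 for UQCRFS1, 0.92 for NDUFB8 and -3.35 for LIN28A. Of 12 fits that left out 1 library, all kept the calls for HSPG2, MGMT, NNAT, SLC15A4 and LIN28A, 11 kept MYH11 (lost without HSPG2 +/- day 30 replicate 2), 9 IFI6 and 7 TNNI3. The other calls were lost in most fits: 5 kept COL18A1 and UQCRFS1, 4 NMRK2, FABP3 and NDRG1, and 3 SPOCK2, LEAP2, TBX5 and NDUFB8. Without WT day 30 replicate 2 or HSPG2 +/- day 15 replicate 1, all of these calls that were kept in 9 or fewer fits were lost, and so were all of them but IFI6 without WT day 30 replicate 3 or HSPG2 +/- day 30 replicate 2. With the replicate block the calls for SPOCK2 (-3.65), FABP3 (-2.46) and TBX5 (-3.15) were lost.

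The reversal of HSPG2 at day 30 was weighed as wrong labels against a late rise of HSPG2 in the edited line. On the 24 other genes that separate the lines at days 0 to 15, 6 libraries of days 20 and 30 lay on the side of the other label, and none of days 0 to 15 did, but the genes were chosen on those days. A rise of HSPG2 in the edited line alone, with every label right, would leave the libraries labelled WT at day 30 below 0.5 on these genes. Their highest score was 1.04, and in 2 of the 3 the 95% interval over resampled genes lay above 0.5 (0.81 to 1.54 and 0.81 to 1.47). It would also leave the 3 libraries labelled HSPG2 +/- at day 30 above 0.5, where the highest score was 0.36, but their intervals reach up to 0.9, so for these 3 a late rise and wrong labels cannot be told apart. Wrong labels, WT day 30 replicates 2 and 3 among them, may therefore account for the reversal at least in part, as a hypothesis. For the library labelled HSPG2 +/- replicate 3 at day 20 the interval lay below 0.5 (-0.01 to 0.49), and 7 of the 24 genes lay nearer HSPG2 +/-. NNAT (32.8 TPM) did not follow the score in that library.

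The fall of sarcomere genes in the libraries labelled WT from day 15 to day 20, with a median of -3.55, was weighed as a smaller share of cardiomyocytes and as an effect of scaling. A scaling factor moves every gene of a library alike, and the median of the sarcomere genes lay at -3.52 from that of all tested genes, with quartiles of -4.38 and -3.22 against -0.53 and 0.41, which argues against the scaling. A smaller share among otherwise unchanged other cells would raise the markers of every other cell type, and the endothelial list fell with a median of -3.28 (-2.52 with genes at 0 held at their bound; adjusted p = 0.000104, and adjusted p = 0.124 with an estimated correlation), with 7 of its 10 members lower over all genes. The stromal list rose (adjusted p = 0.0272, and adjusted p = 0.238 with an estimated correlation), a call lost without WT day 15 replicate 1. A joint loss of cardiomyocytes and endothelial cells, a change within the cells, or a difference between the cultures of the days was not tested, and no biological explanation is set apart from these.

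The libraries of each comparison were also split in other ways. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and the splits with as many genes as the real one, which is included, are given with the real count and the highest other. For the lines it was 1 split at day 0 (15 genes, highest other 1), 1 at day 6 (6 and 0), 1 at day 10 (5 and 0), 1 at day 15 (5 and 0), 5 at day 20 (8 and 2204) and 5 at day 30 (379 and 1898). For the WT steps it was 1 split each, with 11429 genes and 0 from day 0 to 6, 6557 and 1 from day 6 to 10, 5462 and 0 from day 10 to 15, 6142 and 6 from day 15 to 20, and 3459 and 2130 from day 20 to 30. The splits of days 20 and 30 that call several times the real count point to a structure of these libraries other than the labels. Among splits that part all 3 pairs of replicate numbers, the real one gave 8 genes at day 20 and the others 0, 2 and 0. At day 30 the real one gave 379 and the others 0, 0 and 1114, the last with HSPG2 +/- replicate 1 beside WT replicates 2 and 3. For the interaction 22 of 100 splits gave at least 98 genes, with 1154 as the highest other, so chance is not excluded. These splits were not limited to those that part the pairs of replicate numbers, and the one with 1154 did not part them.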

How the results depend on the processing

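Of the tests in this part, the fit of days 0 to 15 and the fit without the 6 doubted libraries were chosen after seeing the data. The counts of the 5 WT steps stayed within 1.5 times under relative log expression factors, no filter, DESeq2 and the replicate block, and those of the 6 line comparisons all moved by more under DESeq2. The cause was not tested where none is given. Depth limits genes of low count, and a count of 0 allows up to 3 counts per library.

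Counts of genes between the lines were as follows. Day 0: 276 with voom, 38 with DESeq2, 257 with the compared groups only, 66 in the fit of days 0 to 15 and 54 without the doubted libraries. Day 6: 3 with relative log expression factors, 76 with voom, 26 with DESeq2, 43 with the compared groups only, 76 in the fit of days 0 to 15 and 43 without the doubted libraries. Day 10: 262, 29, 119, 94 and 47 with voom, DESeq2, the compared groups, days 0 to 15 and without the doubted libraries, and 3 with an absolute log2 fold change above 1. Day 15: 11, 30, 12, 186 and 55 in the same order. Day 20: 5 with no filter, 1 with voom, 359 with DESeq2, 0 with the compared groups only by edgeR (556 at an unadjusted p under 0.05), 811 without the doubted libraries and 4 with an absolute log2 fold change above 1. Day 30: 0 with voom (1197 unadjusted), 1021 with DESeq2 and 0 with the compared groups only (1122 unadjusted).

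For the WT steps the threshold on fold change, which can only remove genes, left 7026, 3378, 2332, 2788 and 1695 genes in order of day. Other moved counts were 12051 with voom and 11067 with the compared groups only from day 6 to 10, 8808 in the fit of days 0 to 15 from day 10 to 15, and 1621 with voom, 327 with the compared groups only and 2276 without the doubted libraries from day 20 to 30. The interaction had 8 genes with voom, 387 with DESeq2 and 0 with the compared groups only (1414 unadjusted).

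With the replicate block the line comparisons gave 19, 11, 5, 6, 91 and 523 genes at days 0, 6, 10, 15, 20 and 30, the WT steps 11378, 6539, 5378, 6154 and 3292, and the interaction 276. The numbers were not taken to pair the libraries at days 0, 6, 10 and 15, where the lowest correlations of deviations were 0.02, 0.02, 0.06 and -0.13. Among lists the block changed 8 calls of 312: imprinted genes at day 15 (adjusted p = 0.0535) and calcium handling at day 20 (0.0738) and ion channels from day 20 to 30 (0.0534) were lost, and maturation, ion channel and heparan sulfate genes from day 0 to 6 (0.0472 each), neural markers from day 10 to 15 (0.0499) and immediate early genes in the interaction (0.0466) passed.

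Leaving out 1 library at a time gave 6 to 10 genes at day 0, 2 to 3 at day 6, 0 to 2 at day 10, 1 to 5 at day 15, 2 to 934 at day 20 and 21 to 2658 at day 30, 10472 to 10696, 5190 to 5477, 4027 to 4683, 4766 to 5746 and 1688 to 4767 in the WT steps, and 27 to 1647 in the interaction. The ranges include the loss of residual degrees of freedom.

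Some values changed sign. Without the doubted libraries, which leaves 1 library labelled WT at day 30, the step from day 20 to 30 in WT gave -0.021 for GATA4, -4.94 for MYH6, -1.28 for MYL2, -0.25 for MYL7, -0.43 for TNNI1 and -0.62 for MYH11, and the lists of sarcomere, maturation and imprinted genes turned (adjusted p = 0.0027, 0.413 and 0.0478). The lone library is assumed to vary like the others. Matrix receptors and smooth muscle markers between the lines at day 20 also turned without the doubted libraries (adjusted p = 0.0181 and 0.000298). Leaving out 1 library turned 6 lists, whose adjusted p over these fits ran from 2.73e-09 to 0.899 for sarcomere genes, 0.00472 to 0.975 for matrix receptors, 1.67e-05 to 0.628 for p53 targets and 0.000439 to 0.787 for smooth muscle markers, all at day 20. For endoderm markers it ran from 0.0024 to 0.56 at day 30 and from 0.00936 to 0.99 in the interaction. The libraries that turned a list were HSPG2 +/- day 20 replicate 1 (sarcomere 0.899, p53 targets 0.011), day 20 replicate 3 (matrix receptors 0.0256, smooth muscle 0.000947) and day 30 replicate 1 (endoderm 0.0413 and 0.00936). The line comparison at day 30 and the interaction have no value without the doubted libraries, and the fit of days 0 to 15 gives one for 7 comparisons only.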

Other observations

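The tests in this part were all chosen after the result was seen. Genes other than HSPG2 told the lines apart from the undifferentiated state on. In the fit of days 0 to 15, the 24 genes of the line score differed with the same sign at each of days 0, 6, 10 and 15, of which 11 were higher and 13 lower in HSPG2 +/-. Independent lists would share 1.34e-05 genes, counted before HSPG2 and the genes left out by the rule for names were set aside. At day 0 in that fit the non-muscle myosin MYH14 changed by -2.82 on the log2 scale. GLT1D1 and SLC15A4, neighbours on chromosome 12, changed by -2.54 and -2.15, the imprinted gene NNAT by -2.71, and MGMT by 3.01. TRIM61 and AC106872.5 overlap on chromosome 4, so that their values of 4.71 and 4.53 can rest on the same reads. These genes were named after their values were seen.

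The pattern weighed here is this set of 24 genes. It held 2 pairs of neighbours within 500 kb, overlapping genes apart, and a share of 0.0227 of 10000 random sets of that size held as many, with a mean of 0.232 pairs. This value is in line with changes at single loci of the edited line that reach neighbouring genes, as a hypothesis. Whether the lower HSPG2 of the edited line may also have moved any of these genes cannot be told apart from other differences of that line, as there was 1 edited line.

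A liver marker set libraries of days 20 and 30 apart from others of their group, as values with no explanation. ALB, the albumin gene, stood at 4.9, 3.93 and 312 TPM in the libraries labelled WT at day 20 and at 0.10, 11.1 and 1456 TPM in those labelled HSPG2 +/-. At day 30 it stood at 73.5, 38.9 and 38.8 TPM in the libraries labelled WT and at 1.47, 2941 and 2564 TPM in those labelled HSPG2 +/-. In WT replicate 1 of day 30 the collagen gene COL3A1 stood at 19837 TPM, against 8163 and 8373 in the others of that label, and made up 5.48% of its counts. The libraries labelled HSPG2 +/- at day 30 held 17991, 14784 and 14722 TPM. WT replicates 2 and 3, both doubted, thus held the least COL3A1 of that day. These genes were named after their values were seen.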
